A study of Mus musculus with 14 samples.

How the data were processed

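Messenger RNA was sequenced from mouse cells in a study of microRNA-218 (miR-218), a small RNA of motoneurons whose 2 genes lie in introns of Slit2 and Slit3. The labels describe 14 samples, of which 13 had a column in the tables used here, and the floor plate sample was not analysed here. Motoneurons were sorted by the green fluorescence of an Hb9::gfp reporter from spinal cords of embryonic day 12.5. Of these, 6 libraries were wild type (WT) and 2 came from embryos lacking both miR-218 genes (double knockout, DKO). V1, V2a and V3 interneurons, labelled with tdTomato through Cre drivers and sorted at the same stage, had 1 library each. Mouse embryonic stem (mES) cells at day 4 of differentiation gave 1 library of Olig2-sorted motoneuron progenitors and 1 of unsorted neural progenitors. Per the labels' protocols, polyadenylated RNA was selected with oligo-dT and libraries were made with a kit that does not mark the strand.

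The deposited values are a signal per gene (23523 gene entries) and per transcript (31702), made by the authors on RefSeq gene models per the file headers. The submitters' processing notes name DESeq, bedtools and the builds mm9 and mm10 without a role or version, and the aligner and counting program are not given in the sources used here. The signal was never negative, its 75th percentile lay between 228 and 234 in every library, and its total between 6.24e+06 and 9.88e+06. It was therefore neither a read count nor a value scaled to a fixed total. Multiplied by transcript length, the low values of single-transcript genes lay within 0.1 of a whole multiple of 1 constant per library for 78.2% to 81.4% of genes, against 20% by chance. These steps gave a length-scaled abundance, scaled between libraries, with approximate depths from 7.37 M reads (DKO replicate 1) to 28.2 M (WT replicate 1). In a transcript of 2000 bases, 3 reads corresponded to a signal of 0.992 in the deepest and 3.94 in the shallowest library. Values below that range carry little information, and in shorter transcripts the same reads give a higher signal. The main test had been written for counts or for normalized values, and the form for normalized values was used because the values were no counts.

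Differences were tested with limma 3.58.1 in R 4.3.3 on log2(signal + 1), with a trended variance prior (limma-trend), for genes with a mean signal of at least 1 over the libraries compared. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(signal + 1) scale, which understates the change of low genes. The 2 DKO libraries were compared with the 6 WT motoneuron libraries, and these 6 with the V1, V2a and V3 libraries taken as 3 members of 1 class. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may in part be technical. Sex-linked signal, given below, shows that the 2 DKO libraries were not repeats of 1 sample, but does not settle this for every WT library. Correlations between libraries reached at most 0.988, so none was a copy of another. On simulated data with 200 changed genes, the DKO design recovered 56% of changes of 1 log2 unit and 91% of changes of 2 log2 units, with 3 false calls among 16260 genes. The interneuron design recovered 48% and 84%, with 13 false calls among 16486 genes.

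Before the data were examined, 31 gene lists were fixed. They cover published miR-218 targets, the host genes, motoneuron identity, cholinergic genes, interneuron and dorsal markers, transmitter systems and receptors, ion channels, vesicle release, axon guidance, Hox genes, progenitor, pluripotency and cell cycle genes, markers of other cells, dissociation stress, apoptosis and sex-linked genes. The 30 lists with at least 3 tested members and 4 lists of miR-218 sites (34 in all) were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted together, and again with an estimated correlation. The fry test, also from limma, asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Sites were matches to AAGCACAA (8mer), AAGCACA (7mer-m8) or AGCACAA (7mer-A1) in annotated 3′ UTRs, where AAGCACA is the complement of bases 2 to 8 of miR-218, and each gene was counted in its strongest class. UTRs and coordinates came from GENCODE M21 on GRCm38 (mm10), where 22924 gene entries matched by transcript accession, 336 by symbol and 263 not at all. For every heptamer found in the UTRs of at least 100 tested genes, the difference in fold change between genes with and without it was taken, adjusted for UTR length. Heptamers were ranked by the t statistic of this difference, not by its size. In simulations with a planted difference of 0.1 log2 units, 18 of 20 planted heptamers ranked first among 14967 genes.

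Because the DKO and interneuron comparisons share the WT libraries, their overlap was set beside 100 simulations without effects and 20 splits of the WT libraries. Groups of 1 library were not tested, and list medians were placed among 10000 random lists of equal size and similar mean signal. Genes named were fixed by rule: the 10 largest rises and falls among called genes with a mean of at least 1 in the higher group and no overlap between groups; up to 4 members per list by adjusted p; every member of the target, host, motoneuron identity and cholinergic lists; and for single libraries the 5 largest differences each way at a signal of at least 10. Gene models without a usual symbol were counted and not named, and some genes that the rule selects are not reported here. Any other gene named was chosen after its values were seen. Alternatives covered the filter, pseudocounts of 0.1 and 5, the transcript table, all 13 libraries in 1 fit, weights on recovered reads (voom), rescaling, the replicate number as a block, each library left out, subsets of the WT libraries and a residual component. Of these, voom, rescaling, the WT subsets and the residual component were added after the values were seen, and methods for counts were not used because the tables hold no counts. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.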

Results

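Transcript abundance was measured in 13 libraries of mouse spinal and stem cell-derived cells. Embryonic spinal motoneurons gave 6 WT and 2 DKO libraries, V1, V2a and V3 interneurons gave 1 each, and mES cells gave 1 library of motoneuron progenitors and 1 of neural progenitors. Approximate depth ranged from 7.37 M reads in DKO replicate 1 and 15.3 M in DKO replicate 2 to between 11.7 and 28.2 M in the WT motoneurons, 16.1 to 17.4 M in the interneurons and 23.0 to 25.6 M in the mES cells. Markers followed the labels. Mnx1, the gene for the transcription factor Hb9 that drove the sorting reporter, had a signal of 2194 to 3995 in WT and 3863 and 4330 in DKO motoneurons, against at most 7.46 in the interneurons. En1 reached 851 in the V1 library, Shox2 3975 in the V2a library and Sim1 808 in the V3 library. Libraries of 1 group also differed in other ways. Rn45s, the ribosomal RNA precursor, had a signal of 10197, 27943 and 14356 in WT replicates 2, 3 and 4, against 644 to 4275 in the other WT libraries and 1647 and 1112 in the DKO libraries.

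**Figure D1:**
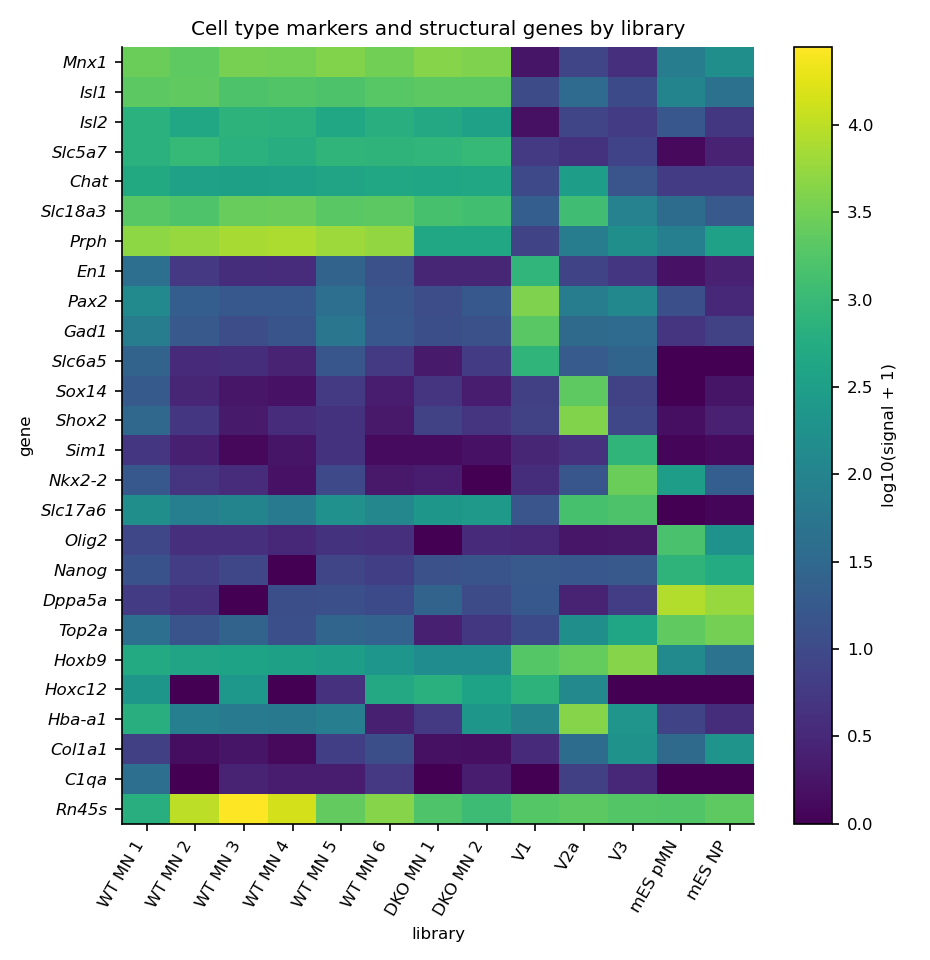
Signal of marker genes in the 13 libraries on a log10(signal + 1) colour scale, with 1 gene per line and 1 library per column (MN, motoneurons; pMN, motoneuron progenitors; NP, neural progenitors). Mnx1 was high in all 8 motoneuron libraries, and Rn45s varied between 644 and 27943 among the 6 WT libraries.

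The comparison of DKO with WT motoneurons asks which transcripts change when miR-218 is lost. Mir218-1 lies at chromosome 5, 48223942 to 48224051, in intron 14 of Slit2 (47983138 to 48307733), and Mir218-2 at chromosome 11, 35616816 to 35616925, in intron 14 of Slit3 (35121224 to 35708507), all on the plus strand of GRCm38. The tables hold no gene entry for either microRNA, so the values do not check the deletions directly. Both host genes, which encode secreted axon guidance ligands, rose. Slit3 had a signal of 607 ± 48.4 (SD, n = 6) in WT and 3708 ± 194 (n = 2) in DKO libraries, a 6.12-fold rise (log2 2.61, SE 0.11, adjusted p = 1.0e-06). Slit2 rose from 1801 ± 352 to 3912 ± 24.9 (log2 1.14, SE 0.18, adjusted p = 0.0057), a call that was lost without DKO replicate 1 (adjusted p = 0.0884) or replicate 2 (0.0809).

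Prph, which encodes the intermediate filament peripherin, fell 13.5-fold, from 6226 ± 1182 to 454 ± 7.86 (log2 -3.75, SE 0.18, adjusted p = 2.2e-06). Anxa2, a calcium-dependent membrane-binding protein, fell 7.91-fold, from 1658 ± 273 to 207 ± 11.7 (adjusted p = 8.5e-06), and Tagln2, an actin-binding protein, fell 7.48-fold, from 1265 ± 243 to 170 ± 58.3 (adjusted p = 1.2e-04). Slc1a2, a glutamate transporter, rose 3.71-fold, from 136 ± 29.0 to 499 ± 5.30 (adjusted p = 6.8e-04). Of 16260 genes tested, 523 were higher and 776 lower in DKO motoneurons with limma, and 170 and 218 of these changed at least 2-fold. The excess of falls reversed with voom weights (503 higher and 443 lower), with WT replicates 2, 3 and 4 alone (1282 and 1170) and with replicate number as a block (120 and 94). None of the 1299 called genes had overlapping groups, whereas 30.7% of all tested genes did not overlap and chance gives 7.14%.

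**Figure D2:**
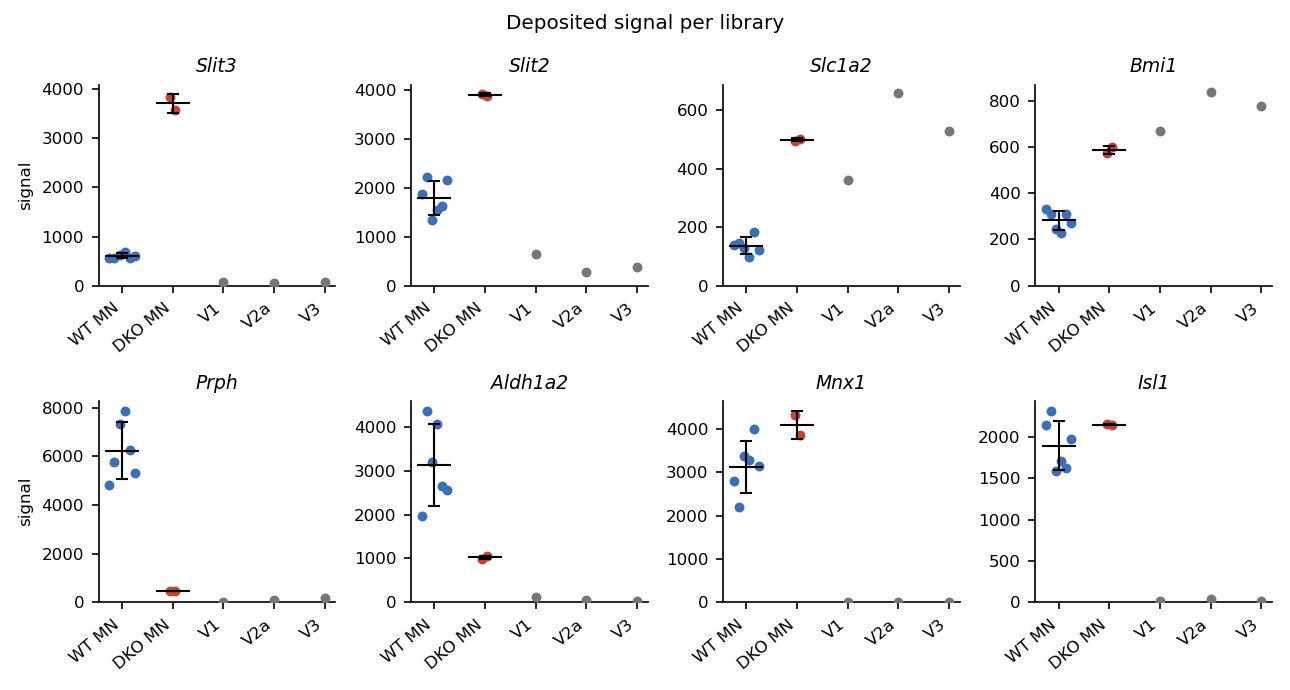
Signal of 8 genes per library (points) in WT (n = 6) and DKO (n = 2) motoneurons, with the mean and SD, and in the single V1, V2a and V3 interneuron libraries. Slit3 was at 3571 and 3845 in the DKO libraries and between 571 and 694 in the WT libraries, and Prph at 448 and 459 against 4826 to 7874.

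The other large falls were in genes of lower signal. Akr1b3, an aldose reductase, was listed at 0 in DKO replicate 1 and at 20.5 in replicate 2, against 68.6 to 163 in WT libraries. Tmem102, Higd1c, Arhgap8 and Rpph1, the RNA component of RNase P, were listed at 0 in both DKO libraries, and in the WT libraries at 13.1 to 25.1, 3.51 to 22.6, 3.04 to 12.9 and 2.03 to 19.6. The long noncoding RNA Haunt fell by 3.42 on the log2 scale, and so did Nudt7 (adjusted p = 0.00505 and 0.00161). Besides Slit3, the largest rises were in Rps27, Trpc2, Bglap, Tnnc2, Trank1, Enkur, Zfhx2os, Fxyd4 and Nts, which encodes the peptide neurotensin. Trank1 rose from 9.60 ± 4.62 to 54.5 ± 7.14 and Nts from 15.5 ± 10.3 to 72.0 ± 32.9. Fxyd4 was listed at 0 in every WT library but WT replicate 5 (1.29), and Bglap in every one but WT replicate 4 (4.07). Both rises thus start near the floor, and without DKO replicate 1 Fxyd4 had no test. The values of Rps27 (220 ± 217 to 1705 ± 785, adjusted p = 0.048) and Bglap are uncertain because near-identical copies exist, and that of Zfhx2os because the reads carried no strand.

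Of 24 measured genes reported elsewhere as miR-218 targets, 7 rose, none fell and 17 did not pass. Besides Slc1a2, they included Bmi1, a Polycomb protein (283 ± 40.5 to 586 ± 17.9), Foxp2, a transcription factor (262 ± 71.0 to 575 ± 0.335), Glce, a heparan sulfate epimerase, Sost, a Wnt antagonist, and the Slit receptor gene Robo2 (700 ± 123.3 to 1075 ± 78.9). Adjusted over the list alone, 10 were higher and 2 lower. The list as a whole did not pass with camera (adjusted p = 0.0619, and adjusted p = 0.703 with an estimated correlation), whereas fry gave 0.0399. Lhx1, Dcc, Hmgb1, Ikbkb and Runx2 had log2 differences between -0.09 and 0.11. Some members may have been chosen by the study on these samples, so the direction of the list is not independent evidence.

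Genes with a miR-218 site in the 3′ UTR rose as a group. Of 3312 tested genes with a site, 308 rose and 91 fell, with a median log2 change of 0.14 against -0.05 in genes without one (camera adjusted p = 6.3e-06, and adjusted p = 0.133 with an estimated correlation). Adjusted over the list alone, 393 were higher and 121 lower. The 709 genes with an 8mer had a median of 0.30, with 132 higher and 9 lower (184 and 22 adjusted over the list alone; adjusted p = 6.7e-13, and adjusted p = 0.133 with an estimated correlation). The 1746 genes with a 7mer-m8 had a median of 0.11 (134 higher and 54 lower, 169 and 66 adjusted over the list alone; adjusted p = 0.0044, and adjusted p = 0.290 with an estimated correlation), and were not called with WT replicates 2, 3 and 4 alone as controls (0.0651). The 857 genes with a 7mer-A1 did not pass as a group (median 0.07, 42 higher and 28 lower, 43 and 29 adjusted over the list alone; adjusted p = 0.0619), and with 1 library left out passed without WT replicate 2 (0.0323). Of 15952 heptamers, AAGCACA, the match to bases 2 to 8 of miR-218, ranked first (t = 15.4), with a difference of 0.20 log2 units over 2455 genes. The overlapping AGCACAA followed (t = 14.6), with a slightly larger difference of 0.21 over 1833 genes. Among the genes named, Bmi1, Robo2 and Sv2a had an 8mer, Slc1a2 and Slit2 a 7mer-m8 and Foxp2 a 7mer-A1.

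**Figure D3:**
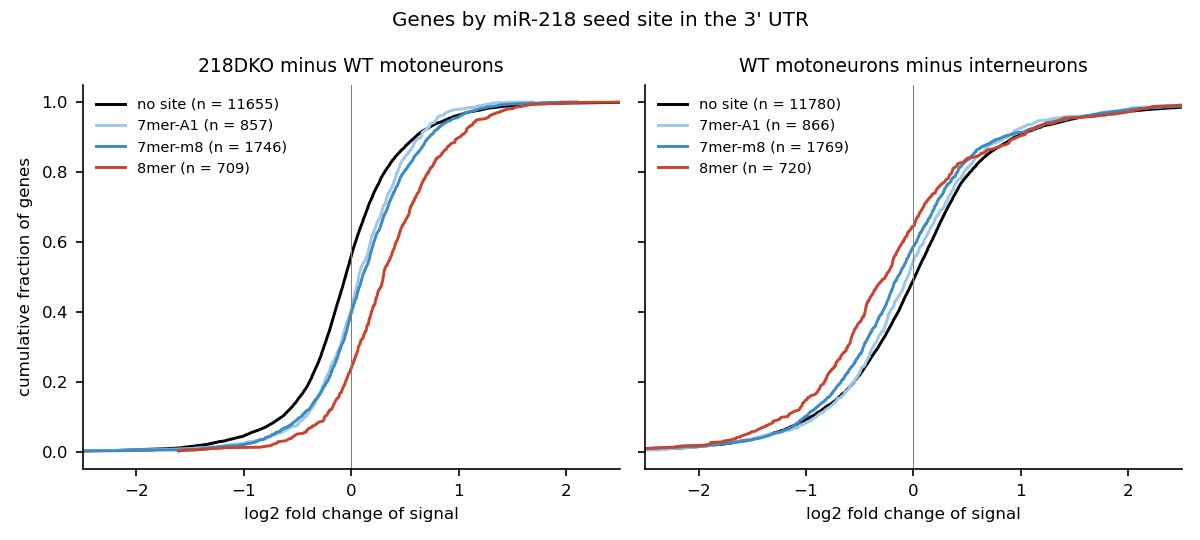
Cumulative fraction of genes against their log2 fold change, for genes grouped by the strongest miR-218 site in the 3′ UTR, in DKO minus WT motoneurons and in WT motoneurons minus interneurons (changes beyond the axis are not drawn). The 8mer genes had a median of 0.30 in the DKO comparison and of -0.26 in the comparison with interneurons.

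Motoneuron identity genes went both ways. Of 16, Slit3 and Ebf2 rose, Prph, Aldh1a2, Ret and Lhx3 fell and 10 did not pass. Adjusted over the list alone, 3 were higher and 8 lower (camera adjusted p = 0.215). Aldh1a2, an enzyme of retinoic acid synthesis, fell from 3134 ± 934 to 1019 ± 43.5, Ret, a receptor for GDNF-family ligands, from 1250 ± 154 to 705 ± 0.322, and the transcription factor gene Lhx3 from 750 ± 145 to 429 ± 57.6. The transcription factor genes Mnx1 (3133 ± 602 and 4097 ± 330, adjusted p = 0.193), Isl1 (1897 ± 300.8 and 2154 ± 4.07, adjusted p = 0.425) and Isl2 (618 ± 124 and 411 ± 91.4, adjusted p = 0.107) did not pass. Of 9 cholinergic genes, Ache, which encodes acetylcholinesterase, fell 1.75-fold and Slc18a3, the vesicular acetylcholine transporter, 1.62-fold, and 7 did not pass (camera adjusted p = 0.408). Adjusted over the list alone, none was higher and 3 were lower, and fry gave an adjusted p of 0.0373. Chat, the enzyme that makes acetylcholine, was at 398 ± 63.7 and 435 ± 14.04, and the choline transporter gene Slc5a7 at 752 ± 122.6 and 891 ± 72.7 in WT and DKO libraries.

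Glutamate receptor genes rose as a group. Of 22, 5 rose, Grm5, Grm3, Grik3 and Grik1 among them, none fell and 17 did not pass, with a median log2 change of 0.45 (camera adjusted p = 4.9e-04, and adjusted p = 0.341 with an estimated correlation). Adjusted over the list alone, 8 were higher. The kainate receptor gene Grik3 rose from 244 ± 54.4 to 462 ± 2.08 and the metabotropic receptor gene Grm5 from 74.0 ± 18.3 to 154 ± 12.6. Of 6 genes of glutamatergic transmission, Slc1a2 rose and 5 did not pass, Slc17a6 among them, and 3 were higher adjusted over the list alone (camera adjusted p = 0.0436, and adjusted p = 0.290 with an estimated correlation). That list was no longer called without WT replicate 2 (0.0693), WT replicate 5 (0.0504) or DKO replicate 1 (0.0779), or with WT replicates 2, 3 and 4 alone (0.0651). Of 18 GABA and glycine receptor genes Gabra5 rose, also when adjusted over the list alone (camera adjusted p = 0.252), and the inhibitory transmission list did not pass (0.966).

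Lists of channels, vesicle release, axon guidance and Hox genes did not pass as groups. Of 39 potassium channel genes Kcnk1 rose and Kcnn1 and Kcnh3 fell (1 higher and 2 lower adjusted over the list alone; adjusted p = 0.384), and of 27 sodium and calcium channel genes Cacnb4 rose and Hcn4 fell (4 and 4; 0.423). Of 32 genes of vesicle release, Sv2a, Syt7 and Pclo rose and Stx1a, Cplx1 and Syt2 fell (4 and 3; 0.785). Stx1a, a membrane protein of vesicle fusion, fell from 1538 ± 163 to 818 ± 51.7, and the vesicle protein gene Sv2a rose from 960 ± 84.5 to 1633 ± 34.0. Of 40 axon guidance genes, Slit2, Slit3, Robo2 and Epha7 rose and Unc5a, Unc5b, Efna3 and Nrp1 fell (5 and 8; 0.730). Of 33 Hox genes, Hoxb9 fell from 362 ± 104 to 143 ± 0.126 (1 lower; 0.420). Of 14 apoptosis genes, Cdkn1a and Zmat3 fell (3 higher and 2 lower; 0.515).

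Cell cycle genes fell as a group, with Mcm2, Top2a, Aurkb and Aurka lower among 25 and 21 not passing (5 lower adjusted over the list alone; camera adjusted p = 0.0082, and adjusted p = 0.838 with an estimated correlation). Aurkb was listed at 0 in both DKO libraries and at 2.70 to 11.1 in the WT libraries, and Aurka lost its call when any 1 library was left out. Several other-cell markers varied among WT libraries. WT replicate 1 held the highest WT signal of Top2a (41.1, against 1.502 and 4.31 in the DKO libraries), En1 (40.8), Hba-a1 (604) and C1qa (40.9). With WT replicates 2, 3 and 4 alone as controls, the cell cycle list was not called (camera adjusted p = 0.211), nor was it with fry (adjusted p = 0.194). Of 20 neural progenitor genes the intermediate filament gene Vim fell from 4292 ± 611 to 1979 ± 242 (1 lower adjusted over the list alone; adjusted p = 0.112). No gene passed among the markers of V3 neurons (6 genes, 1 higher adjusted over the list alone; adjusted p = 0.494), V0 and dorsal neurons (14; 0.173), glia (9; 0.173), blood (9; 0.661), microglia and macrophages (8; 0.339), endothelium (7; 0.785), mesenchyme and meninges (6; 0.339) and Schwann cells and neural crest (7; 0.423). None passed among pluripotency (6; 0.623), dissociation stress (12; 0.436) or sex-linked genes (5; 0.966) either. Foxp2 alone rose among 12 V1 markers (1 higher adjusted over the list alone; 0.966), Lhx3 alone fell among 9 V2 markers (2 higher and 1 lower; 0.785), Slit2 alone rose among 13 floor plate markers (1 and 1; 0.124, and 0.0492 without WT replicate 4) and Runx1 alone fell among 6 sensory neuron markers (1 lower; 0.420).

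With 2 DKO libraries, the count of calls rested on both. Without DKO replicate 1, 97 genes passed and without replicate 2, 141, with the remaining library assumed to vary like the WT libraries, and of 59 selected genes that passed, 10 and 9 still did. Leaving out WT replicate 2 gave 2032 genes and leaving out WT replicate 4 gave 827, and 43 to 56 of the 59 selected genes passed with any 1 WT library left out. Slit3, Prph, Anxa2, Tagln2, Slc1a2, Akr1b3, Tmem102 and Nudt7 passed in each of these fits.

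The comparison of WT motoneurons with interneurons asks which genes mark motoneurons at this stage. Mnx1 was the largest difference, with a signal of 3133 ± 602 (n = 6) in motoneurons and 3.80 ± 3.39 (n = 3) in interneurons (log2 9.60, adjusted p = 2.3e-07). The LIM-homeodomain genes Isl2 and Isl1, Prph, the choline transporter gene Slc5a7, Barx2, Chodl, Etv4 and Aldh1a2 were also among the 10 largest, between 54.9-fold and 139-fold higher. Uts2, which encodes the peptide urotensin 2, was at 89.9 ± 26.2 in motoneurons and listed at 0 in the 3 interneuron libraries. The host genes Slit3 (607 ± 48.4 against 69.1 ± 8.63) and Slit2 (1801 ± 352 against 441 ± 193) were higher in motoneurons. Lowest in motoneurons relative to interneurons were Zfp433, Trpc2, Cdh3, Sox21, Igfbpl1, Pmfbp1, H2-Q9, Pax1, Synpr and Gli3. Leaving out 1 library, H2-Q9 did not pass in 6 of 9 fits, Pax1 in 7 (1 of them without a test) and Sox21 in 1, and of 109 selected genes that passed, 82 did so in every fit. Synpr, a vesicle protein gene, was at 39.5 ± 6.07 against 412 ± 181, and H2-Q9 is uncertain because it belongs to a family of similar genes. Of 16486 genes tested, 2921 were higher and 2498 lower in motoneurons, 1229 and 997 of them at least 2-fold, and 4612 of these 5419 had groups that did not overlap (chance gives 2.38% of genes).

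Of 16 motoneuron identity genes, 13 were higher and 3 (Ebf2, Lhx3 and Lhx4) did not pass (15 higher adjusted over the list alone; camera adjusted p = 3.7e-13, and adjusted p = 0.0044 with an estimated correlation). Lhx3 was at 3293 in the V2a library, above the WT motoneuron mean of 750 ± 145. Of 9 cholinergic genes, Slc5a7, Ache, Slc18a3 and Chat were higher and 5 receptor and transporter genes did not pass (5 higher adjusted over the list alone; adjusted p = 0.0133, and adjusted p = 0.193 with an estimated correlation; 0.0534, not called, with WT replicates 1, 5 and 6 alone). Of 33 Hox genes, none was higher and 23 were lower (24 adjusted over the list alone; adjusted p = 3.9e-10, and adjusted p = 0.113 with an estimated correlation). Hoxb9 was at 362 ± 104 against 2898 ± 1262 and Hoxb6 at 217 ± 76.8 against 1510 ± 171.

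The lists of GABA and glycine receptors, vesicle release and potassium channels were higher in motoneurons as groups, though in the V1 library alone vesicle release and potassium channels lay at the 60.53 and 35.235 percentiles of random lists (V1 minus motoneurons). Of 17 GABA and glycine receptor genes 11 were higher and Glra1 lower (12 and 1 adjusted over the list alone; camera adjusted p = 9.9e-04, and adjusted p = 0.498 with an estimated correlation). Gabra2 was at 283 ± 92.6 against 46.0 ± 10.1. Of 32 genes of vesicle release 16 were higher, Stx1a, Cplx1, Syt2 and Cplx2 among them, and Sv2a and Pclo lower (16 and 2; adjusted p = 0.0014, and adjusted p = 0.440 with an estimated correlation). Of 39 potassium channel genes 15 were higher, Kcna5, Kcnh3 and Kcnt2 among them, and Kcnc1, Kcnj9 and Kcnk2 lower (17 and 5; adjusted p = 0.0272, and adjusted p = 0.684 with an estimated correlation). Sodium and calcium channel genes (8 higher and 5 lower of 27, 9 and 6 adjusted over the list alone; adjusted p = 0.288), led by Scn9a and Cacna1e, and glutamate receptor genes (6 and 3 of 22, likewise 6 and 3; 0.252), led by Grin2a and Grin3a, did not pass as groups, although glutamate receptors did without V1 (0.00855). Of 40 axon guidance genes 15 were higher and 7 lower (15 and 9; 0.252). Nrp1, a semaphorin receptor gene, was at 1501 ± 232 against 101 ± 57.0, the netrin receptor gene Unc5c at 447 ± 92.5 against 38.8 ± 24.1, and Plxna2 at 199 ± 33.3 against 719 ± 82.5.

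Cell cycle genes were lower in motoneurons (Ccne1 higher and 8 of 25 lower, Mcm7 and Mcm5 among them, 1 and 9 adjusted over the list alone; camera adjusted p = 0.0013, and adjusted p = 0.684 with an estimated correlation), and so were mesenchyme and meninges markers (Col1a2, Col3a1, Pdgfra, Lum and Foxc1 of 10, 8 adjusted over the list alone; adjusted p = 0.0192, and adjusted p = 0.684 with an estimated correlation). Both lists varied with the interneuron library. Top2a was at 413 in V3, 163 in V2a and 8.87 in V1, and Col1a1 at 193, 37.0 and 2.40. Without the V3 library neither passed (adjusted p = 0.0540 and 0.118), nor did potassium channels (0.138, and 0.102 without the V2a library). With fry, cell cycle (adjusted p = 0.102), mesenchyme (0.0909) and potassium channels (0.0577) did not pass either. With WT replicates 1, 5 and 6 alone the mesenchyme list was not called (0.173), and with WT replicates 2, 3 and 4 alone potassium channels were not (0.0683). Blood markers did not pass (Alas2 lower of 10, none adjusted over the list alone; 0.0532), with Hba-a1 at 4296 in V2a, and became called without WT replicate 1 (0.0228) or V1 (0.0023). Neural progenitor genes (2 higher and 7 lower of 20, 3 and 12 adjusted over the list alone; 0.0540) also became called without WT replicate 1 (0.0228) or V1 (0.0041).

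Lists of interneuron and dorsal markers did not pass: V1 (Pax2 and Pax8 lower of 12, none adjusted over the list alone; 0.288), V2 (Lin28b lower of 10, likewise 1; 0.235), V3 (none of 6; 0.135), and V0 and dorsal markers (Pou4f1 higher, Pax3, Ptf1a, Gbx1 and Lbx1 lower of 16, 1 and 6 adjusted over the list alone; 0.162, and 0.0309 without WT replicate 1). The inhibitory transmission list did not pass (0.149), with Slc6a9 higher and Gad2, Slc32a1 and Slc6a5 lower, and glutamatergic transmission had Slc1a1 higher and Slc1a2 and Slc17a8 lower of 6 (1 and 2 adjusted over the list alone; 0.785). When V1 was left out the V3 list passed (0.0041), and when V3 was left out the V1 list passed (0.0372). Several single genes of this paragraph depended on 1 library. Leaving out 1 library, Slc6a9, Slc17a8 and Gbx1 did not pass in 7 of 9 fits, and Pax2 and Slc6a5 in 5. Gad2, Pax8, Jun, Prdm12, Fabp7 and Ednrb did not pass in 6. Floor plate markers had Shh, Spon1 and Slit2 higher and Slit1 lower of 13 (0.617), glial markers Mbp higher and Fabp7 and Pdgfra lower of 10 (0.243), sensory neuron markers Pou4f1 and Runx1 higher, and Prdm12 among 2 lower, of 7 (0.782), and Schwann and neural crest markers Fabp7 and Ednrb lower of 7 (0.235), each with equal counts adjusted over the list alone. Apoptosis genes had 4 higher, Ccng1 and Cdkn1a among them, and Mdm2 and Trp53inp1 lower of 13 (5 and 2 adjusted over the list alone; 0.480). Dissociation stress genes had Jun and Hsph1 higher of 12 (1 adjusted over the list alone; 0.667), and pluripotency genes Lin28a lower of 5 (likewise 1; 0.475). No microglial (9; 0.823), endothelial (8; 0.162, and 0.0043 without V1) or sex-linked gene (5; 0.235) passed.

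Genes with a miR-218 site were lower in motoneurons than in interneurons. The 720 genes with an 8mer had a median log2 difference of -0.26, with 216 lower and 104 higher (241 and 110 adjusted over the list alone; camera adjusted p = 0.0031, and adjusted p = 0.389 with an estimated correlation). The 7mer-m8 genes (median -0.15; 395 lower and 268 higher of 1769, 411 and 277 adjusted over the list alone; adjusted p = 0.0987) and 7mer-A1 genes (median -0.05; 149 and 148 of 866, 150 and 150; adjusted p = 0.535) did not pass. All 3355 genes with a site lay at the threshold (760 lower and 520 higher, 790 and 539 adjusted over the list alone; adjusted p = 0.0497, and adjusted p = 0.440 with an estimated correlation), and lost the call without WT replicate 1 (0.0666), 3 (0.0585), 4 (0.0574) or 6 (0.0602), V1 (0.0837) or V3 (0.0540). AAGCACA ranked first of 15963 heptamers, with a difference of -0.17 log2 units over 2489 genes. Of the 24 published targets, 9 were lower in motoneurons, with Bmi1 (283 ± 40.5 against 764 ± 86.3) and Slc1a2 (136 ± 29.0 against 517 ± 149) among them, and Tead1 and Sost were higher (11 and 3 adjusted over the list alone). The target list did not pass (adjusted p = 0.0531) and did without V2a (0.0405) or V1 (0.0194).

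Genes that changed in DKO motoneurons tended to differ in the same direction between interneurons and WT motoneurons. Among 16117 genes tested in both, the covariance of the 2 log2 fold changes (DKO minus WT, interneurons minus WT) was 0.206, against 0.0468 in simulations without effects, which share the WT libraries in the same way. The difference was 0.160, and with separate WT libraries for each comparison the covariance averaged 0.167 (0.0890 to 0.203 over 20 splits). The correlation across genes, which are not independent replicates, was 0.382, against 0.287 in the simulations and 0.289 with separate WT libraries. Of 776 genes that fell in DKO, 516 were also lower in interneurons (141 for independent lists, 315 in simulations without effects) and 12 were higher. Of 518 genes that rose, 267 were also higher in interneurons (78.0 and 197) and 27 lower, Slit2 and Slit3 among these. The simulated lists had the observed sizes but came from noise alone, without interneuron differences. The values of 315 and 197 are therefore not the part of the real overlap owed to the WT libraries. With separate WT libraries, shared falls were 2.58 to 6.50 times the number for independent lists, and shared rises 2.10 to 7.76 times. Rises were called higher in interneurons for 162 of 266 genes with an 8mer or 7mer-m8 and 70 of 170 without any site, and falls lower for 47 of 63 and 442 of 670. Genes with a 7mer-A1 as their best site or without a 3′ UTR sequence were left out of these counts. Values without effects were not simulated for these subsets.

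**Figure D4:**
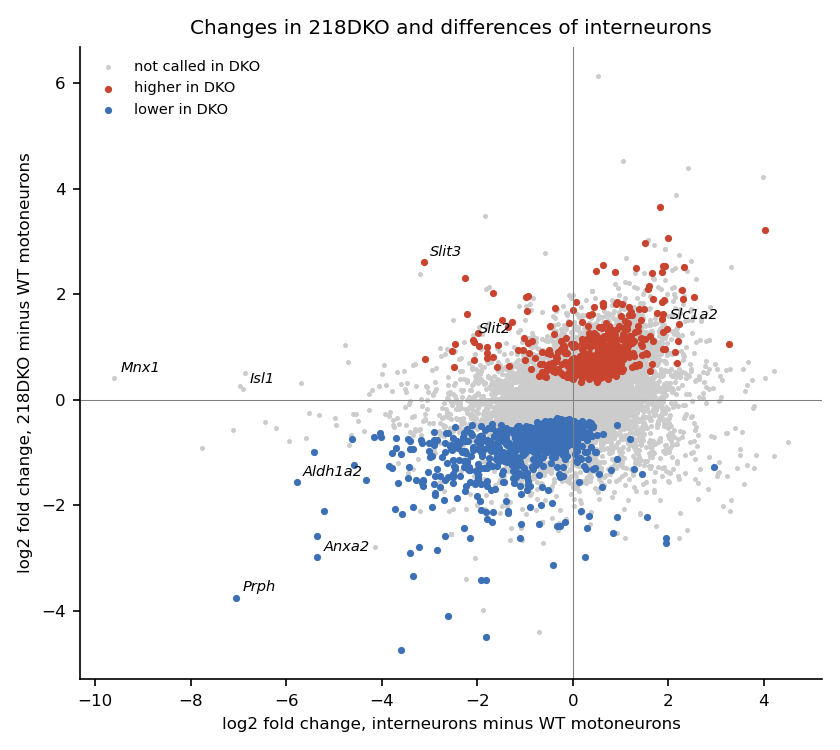
Log2 fold change of 16117 genes in DKO minus WT motoneurons (vertical) against interneurons minus WT motoneurons (horizontal), with genes called in the DKO comparison in red (higher) and blue (lower). Of 776 falls, 516 were also lower in interneurons; both axes use the same WT libraries, so part of the slope comes from these.

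Each interneuron library carried the genes of its type, with no replicate check. In the V2a library Shox2 (3975 against 7.15 ± 11.6 in WT motoneurons) and Sox14 (2190) were the largest reported differences, followed by Hbb-b2 and Hbb-bt, which held the same value (284) and share reads. In V1 they were Aqp6 (989 against 3.85 ± 2.24), Pax2, Slc30a3, Pax8 and the glycine transporter gene Slc6a5 (807), and in V3 Nkx2-2 (2858 against 5.37 ± 5.83), Sim1, Olig3, the axon guidance receptor gene Robo3 (6694) and Pax1. Mnx1 was among the 5 lowest in each, with Slc5a7, Barx2, Akr1b3 and Chodl in V2a, Prph, Isl2, Islr2 and Isl1 in V1, and Chodl, Isl1, Barx2 and Isl2 in V3. The V2a library held the vesicular acetylcholine transporter gene Slc18a3 at 1202, and Slc17a6, a vesicular glutamate transporter gene, was at 1427 in V2a, 1581 in V3 and 13.6 in V1. The V1 markers had a median log2 difference of 3.03 in V1, the V2 markers of 2.86 in V2a and the V3 markers of 7.10 in V3, each at the 100th percentile of random lists. The 8mer genes had medians of 0.27, 0.26 and 0.26 in V1, V2a and V3, also each at the 100th percentile. Those random lists were not matched for UTR length, and all these medians share the WT libraries, so they are not separate checks of the site.

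The mES-derived progenitors, also without replicates, stood farther from motoneurons. In the motoneuron progenitors Mt2 and Mt1, which encode metallothioneins, Stra8, a retinoic acid-responsive gene, Nkx2-9 and the stem cell gene Dppa5a were the largest differences, with Dppa5a at 8722 against 6.57 ± 4.49 in WT motoneurons. Fxyd7, Nyap2 and Ache were listed at 0 in them, against 3033 ± 377, 922 ± 181 and 898 ± 127, and Rbfox1 and Actl6b were at 0.622 and 0.521. In the neural progenitors Stra8 (9926), Mt2, Mt1, Cyp26a1, which encodes a retinoic acid-degrading enzyme, and Cldn4 (2809, listed at 0 in all WT motoneurons) led, and Fxyd7, Ptpn5, Slitrk1, Rab3c and Hoxc10 were lowest. Olig2 was at 1495 in the motoneuron progenitors and 191 in the neural progenitors, and neural progenitor genes had a median difference of 2.15 between these libraries, at the 100th percentile. Mest, an imprinted gene, was at 10762 against 10.5, and Rnaset2b, Zscan4e and Crygc followed. Eif2s3y, Ddx3y and Uty, on the Y chromosome, were listed at 0 in the motoneuron progenitors and at 892, 258 and 154 in the neural progenitors, and Raet1b and Serpinb9e were also listed at 0 against 153 and 62.8. Against WT motoneurons the 8mer genes had medians of -0.15 in the motoneuron progenitors and -0.01 in the neural progenitors, at the 1.06th and 1.01st percentiles. The random lists used here were not matched for UTR length either.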

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

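Each gene selected for the report was checked within the 6 WT motoneuron libraries for a single library far from the other 5, measured by its gap to the nearest value relative to the whole range. Of 269 genes, 48 had such a library, and chance gives about 1 in 20. No test of a cause was made for these values.

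In WT replicate 1, 32 genes had their far value at the upper end. They included markers of interneurons and dorsal neurons: Pax2 (130.2), Pax8 (69.9), Gad2 (52.5), Lbx1 (46.6), Olig3 (41.9), Shox2 (30.6), Barhl2 (28.5), Sox14 (17.3), Pax3 (13.4), Lhx2 (10.98) and Robo3 (176). Progenitor genes in the same library were Hes5 (50.3), Pax6 (40.5) and Olig2 (7.86). Microglial and immune genes were C1qa (40.9), C1qc (31.3), Cx3cr1 (28.3), Csf1r (26.2), Aif1 (14.3), Fcer1g (13.05) and Ptprc (2.68). Blood genes were Hba-x (201), Alas2 (6.01), and Hbb-b2 and Hbb-bt, which hold the same value (10.5). The sensory neuron gene Prdm12 was at 8.82, and the others were Igfbpl1 (338), Hoxb6 (366), Zfp433 (59.0) and Col1a2 (5.65).

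In WT replicate 2 the far values were high for Hmgb1 (4236), Rbfox1 (2320), Ccng1 (578), Anxa7 (120.1) and Gabrg1 (66.9), and low for Pxn (174) and Actl6b (1282). In WT replicate 3 they were high for the stress and apoptosis genes Cdkn1a (178) and Atf3 (83.5) and for Aurka (48.4). Bglap was high in WT replicate 4 (4.07), Fxyd4 (1.29) and Cyp26a1 (1.99) in WT replicate 5, and Shh (128) and Sost (19.0) in WT replicate 6. Lhx4 was low in WT replicate 5 (415).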

How the results depend on the processing

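The voom weights, rescaling, WT subsets, residual component and GC content, and for gene lists and sites also the pseudocounts, transcript table and joint fit, were chosen only after the data were seen. The 1299 genes of the DKO comparison became 2859 with a residual component (all 1299 shared), 2315 with WT replicates 1, 5 and 6 (1182 shared) and 2452 with WT replicates 2, 3 and 4 (1084 shared); with 1 library left out they ranged from 97 (without DKO replicate 1) to 2032 (without WT replicate 2). The residual component was taken from what the group fit left over, so it could not move the fold changes and could only narrow the spread. The rise to 2859 is therefore no evidence of a stronger effect. With replicate number as a block the 1299 genes became 214 (154 shared). That fit set only WT replicates 1 and 2 against the DKO libraries, and the labels give no pairing, so this is no evidence of a weaker effect. Residuals of equal numbers did not correlate (r -0.06 and -0.01), but those of the 2 DKO libraries mirror each other, so these r values say little. Its 3 called gene lists became 5 without a filter, 10 with the block, 9 with WT replicates 1, 5 and 6, 1 with WT replicates 2, 3 and 4 and 0 with an estimated correlation (2 to 4 with 1 library left out). Sites there gave 0.133 with an estimated correlation and 1.66e-06 to 9.47e-05 with 1 library left out. For motoneurons against interneurons, 5419 genes became 3536 with WT replicates 1, 5 and 6 (3684 to 5672 with 1 library left out), and 8 lists became 1 with an estimated correlation and 6 to 14 with 1 library left out, the most without V1. Sites there (0.0497) gave 0.0729 without a filter, 0.0514 in the transcript table, 0.0518 in the joint fit, 0.0595 with 1 mean per type, 0.0977 with WT replicates 2, 3 and 4, 0.440 with an estimated correlation and 0.0289 to 0.0837 with 1 library left out. With fry, 4 lists were called in the DKO comparison, 2 of them among its 3. Cell cycle was not (adjusted p = 0.194), and the target (0.0399) and cholinergic (0.0373) lists were. In the other comparison fry called 7 lists, 5 of them among its 8. Cell cycle (0.102), mesenchyme (0.0909) and potassium channels (0.0577) were not called there, and the target (0.0027) and axon guidance (1.7e-04) lists were. The overlap covariance moved to 0.167 with separate WT libraries. Beyond these points, the cause of the changes was not tested. The larger number of falls in the DKO comparison (776 against 523) reversed with voom weights (443 against 503), WT replicates 2, 3 and 4 (1170 against 1282) and the block (94 against 120), and the larger number of higher genes in the other (2921 against 2498) reversed with WT replicates 2, 3 and 4 (2492 against 2505). No called value of a named gene, list or site changed sign, but 1 other gene was called in the opposite direction in the transcript table of the interneuron comparison. Of 3078 values for single genes in the DKO comparison, 2701 kept their side of the threshold, 264 lost and 113 gained a call, and of 3050 in the other, 2773, 202 and 75. The fit with a surrogate variable, the count-based alternatives and the floor plate sample were not run. Depth limits genes whose signal is below 3.94 in DKO replicate 1.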

Other observations

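The tests of annexin and S100 genes, of UTR length and GC content, of the number of matches within a site class, of Rn45s for the genes with sites, of sites in the host transcripts, of interneuron and other-cell genes in the DKO sorts, of a uniform fall of motoneuron-restricted genes and of other sample splits were chosen only after the result was seen. Several annexin and S100 genes, which encode calcium-binding proteins, stood among the falls in DKO motoneurons. Besides Anxa2, they were S100a11 (372 ± 63.2 to 77.0 ± 20.9), Anxa5 (500 ± 69.3 to 117 ± 10.5), Anxa6 (358 ± 37.0 to 128 ± 12.1), S100a10 (4284 ± 815.7 to 1777 ± 52.8), Anxa7 (96.7 ± 11.96 to 51.0 ± 19.0) and Anxa4 (19.7 ± 5.99 to 6.69 ± 0.242), while S100a13 (4.43 ± 1.33) was listed at 0 in both DKO libraries. Of all 14 tested members, 8 fell and none rose, and camera gave 2.19e-07 (unadjusted, two-sided; 0.00335 with an estimated correlation). The median log2 change was -1.19, and between -1.37 and -0.90 over 20 settings. The family was noticed in the data and tested on the same data, so its fall remains a hypothesis.

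Values outside the comparisons also differed between libraries. Hoxc12, a gene of the lumbosacral level, had a signal of 672 and 382 in the DKO libraries, of 222, 234 and 484 in WT replicates 1, 3 and 6, of 3.36 in WT replicate 5, and was listed at 0 in WT replicates 2 and 4. Xist, expressed from the inactive X chromosome, was at 1857 in DKO replicate 1 and 0.767 in DKO replicate 2, and the Y-linked Ddx3y at 0 and 209. WT replicates 3 and 6 had Xist at 1.19 and 1.64 with Ddx3y at 136 and 165. WT replicate 1 had both, at 869 and 69.0. The DKO libraries were therefore not repeats of 1 sample, nor was WT replicate 1 a repeat of WT replicates 3 or 6.

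The higher signal of genes with a miR-218 site in DKO motoneurons was weighed first. The tables argue against UTR length and GC content as its cause, since 8mer genes lay 0.32 log2 units above 10000 sets matched for both (0.30 against -0.02, central 95% of sets -0.05 to 0.00). With the WT libraries of high Rn45s signal left out, the AAGCACA difference was 0.18 (0.18 to 0.22 over all settings, ranked first in each), so these libraries are not its source. Matches were counted over all distinct annotated UTRs of a gene, so 1 site shared by 2 UTRs counted as 2 matches. Genes with 2 or more such matches (1008) rose more than genes with 1 (1447), by 0.14 at matched length of the longest UTR (95% interval 0.11 to 0.20). The one-sided permutation p was 1e-05, the smallest these permutations can give. Since genes with more matches more often hold an 8mer, the difference was also taken within 8mer and 7mer-m8 genes at matched length. It was 0.15 (0.10 to 0.19, one-sided permutation p = 1e-05). Neither difference separates more sites from more annotated UTRs, so no effect of the number of sites is concluded. Relief from repression by miR-218 is a candidate explanation that these tests leave standing, and the list p of 0.133 with an estimated correlation limits it.

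Genes lower in both DKO motoneurons and interneurons (516, median log2 change -0.79) were weighed second. A lower share of motoneurons in the DKO sorts predicted, before the result was seen, that motoneuron-restricted genes would fall by a similar amount. The 22 such genes had a median of -0.56, within their spread (0.31) of that value, with 6 called lower and none higher. These 6 are also among the 516 genes, so the 22 are not a fully separate check. The single genes argue against a lower share as the whole cause, since it would lower them alike and their values ran from -3.75 to 0.50. Of the 22, 7, Isl1 and Mnx1 among them, had 95% intervals above -0.79 and 4 had intervals below it. The value of -0.79 came from genes selected for falling, some of the 7 cleared it only narrowly, and Mnx1 drove the sorting reporter. The markers of other cells, which a lower share would raise, did not rise: of 14 lists none was called higher and 1, cell cycle, was lower. With WT replicates 1, 5 and 6 alone 7 were lower, floor plate, mesenchyme, progenitor, glia, microglia and V0 and dorsal markers besides. With WT replicates 2, 3 and 4 alone none was lower, and none was higher with either. Also, 12 markers of V1, V2a and V3 neurons gave a summed share of -0.95%, each at most 0.225%, where 42.3% would be needed. Cells without markers in these lists could still contribute, so a lower share as part of the cause stays open, as does a less mature state of the DKO motoneurons, which was not tested. For an axial difference, 96.5% of the fall stayed when Hox 11 to 13 signal was a covariate. Without the WT libraries of high Rn45s signal, 90.3% stayed. The 516 genes had been called against all 6 WT libraries with no overlap between groups, so most of their fall was bound to stay. The 2 values therefore cannot decide whether either difference contributes.

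The higher signal of the host genes Slit3 and Slit2 was weighed last. If the chromosome regions around the loci differed between the mice, nearby genes might change too: of 74 genes within 5 Mb, 10 were called (13.5%, against 7.998% elsewhere; one-sided Fisher exact p = 0.0707), which leaves this open. The annotated 3′ UTRs of Slit3 (365 bases, all joined) held 0 miR-218 sites, so loss of repression through them is not the cause of its rise. Those of Slit2 (4763 bases, all joined) held 5 matches, where a site shared by several UTRs counted once in each. Loss of repression through these may contribute to the rise of Slit2. An effect of the deletions on host transcription or splicing was not tested.

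Of the 28 ways to pick 2 of the 8 motoneuron libraries, 1, the real one, gave as many as 1299 genes, and the highest other gave 27. Of the 84 ways to pick 3 of the 9 WT motoneuron and interneuron libraries, 1, the real one, gave as many as 5419, and the highest other gave 592. The real grouping thus gave the most genes in both, and 1 in 28 and 1 in 84 are the smallest shares these splits can give. Every other split leaves the real group difference in the spread within its groups, which lowers its count, so the splits cannot exclude chance.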
